A study of Homo sapiens with 152 samples.

How the data were processed

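Gene expression was measured by bulk RNA sequencing in 152 libraries of cells sorted from the blood of healthy subjects and of patients after cardiac arrest (post-CA). Blood mononuclear cells were sorted by flow cytometry into NK cells with and without Tim-3, an inhibitory receptor encoded by HAVCR2, and into monocytes with and without Nectin-2, a surface ligand encoded by NECTIN2. Per the labels' protocols, 1000 cells went into each library, libraries were made with Smart-seq2, a full-length cDNA method, with a final PCR of 12 cycles, and paired reads of 38 bp were sequenced in batches. No label gives the batch, the donor or the sampling time of a library, so none of these could be a term of a fit and the fractions of one person could not be paired. The series text names 12 healthy subjects and 28 patients, while each monocyte fraction has 32 post-CA libraries. Some patients therefore gave more than one library to a fraction, and the p-values, which treat libraries as independent, may be too small.

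The authors deposited one table of raw read counts per gene symbol, with 50657 lines, of which 5 hold the special categories that htseq-count writes. The genome was GRCh37 per the submitters' processing notes; the aligner, the counting program, the annotation and the strand setting are not stated. Over all libraries 19.0% of reads were counted on genes, 57.3% matched no annotated feature, 15.0% were not aligned, 7.88% had more than 1 alignment and 0.836% were ambiguous. Sex-linked genes (416) were left out for privacy, which left 50236 genes. Symbols, GC content, gene length and gene type were taken from GENCODE 29, which is built on GRCh38, so no coordinates are given; 92.5% of the NK genes tested and 91.6% of the monocyte genes tested had a match there. Of 266 named genes, 42 overlap another gene on the opposite strand, among them HLA-DPA1, HLA-DPB1, PSMB8, PRELID1 and CIITA. Their counts may hold reads of that neighbour, because Smart-seq2 does not mark the strand. Reads of close paralogs (HSPA1B and HSPA1A, HBA2 and HBA1, the HLA genes, CCL3 and its copies) may be lost or shared too, because they can have more than 1 alignment.

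A library was called low in quality when its number of detected genes lay more than 3 median absolute deviations below the median of its lineage. This held for 7 libraries: 3 of Nectin-2-positive monocytes and 1 each of Tim-3-positive and Tim-3-negative NK cells from patients, and 2 nearly empty libraries of Nectin-2-negative monocytes from healthy subjects with under 10000 gene reads each. All libraries stayed in the tests, and every count was repeated without these 7. Means and SDs of CPM (read counts scaled to the size of the library) and counts of libraries in which a gene lay above or below a median are over the other libraries. For list levels and shares of reads such counts are over all libraries. No pair of libraries was identical.

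The test was the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr and 1 mean per group, fitted over all libraries of a lineage (11220 genes in NK cells, 11405 in monocytes) or over all 152 libraries (12856 genes). Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and an adjusted p under 0.05 passed. The biological coefficient of variation was 0.368 in NK cells and 0.416 in monocytes. Values after ± are SEs for log2 fold changes and SDs for CPM. The 11 comparisons were post-CA against healthy in each of the 4 fractions, marker-positive against marker-negative cells in each lineage and arm, the difference of the post-CA effect between the fractions of each lineage, and the difference of that effect between lineages. Counts were also simulated from the gene means, library sizes and dispersions of each lineage, with known changes added. Such counts hold no repeated donors, no batches and no RNA of other cells that moves with the arm. On them edgeR found 70.1% of 2-fold and 98.5% of 4-fold changes in Tim-3-positive NK cells with 2 false calls among 131. For the differences between fractions it found 52.2% of 2-fold changes in NK cells and 26.9% in monocytes.

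The comparisons, the gene lists, the rule for named genes and most alternatives were set before the data were examined. Named genes were those with the largest changes among genes past the threshold with a mean log2 CPM of at least 5 (at least 3 where fewer than 20 genes passed). They numbered 10 in each direction for post-CA against healthy and 5 for the other comparisons. HAVCR2, NECTIN2 and, in NK cells, IFNG were added, with the 4 members of each list with the smallest adjusted p. XIST, Y-linked genes, HLA genes outside class II, KIR, immunoglobulin and T cell receptor genes, unnamed clones and pseudogenes were left out, as was 1 other gene that met the rule. Single genes named outside this rule are said to be so where they appear.

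The 29 gene lists were cytotoxic effectors, NK cytokines and chemokines, NK receptors, the immune checkpoint axis, type I interferon-stimulated genes, interferon-gamma response, HLA class II, inflammatory cytokines, immediate early genes, heat shock, glucocorticoid-responsive genes, alarmin and immature monocyte genes, classical monocyte markers, non-classical monocyte markers, CD56-bright NK markers, CD56-dim NK markers, pattern recognition and inflammasome, hypoxia and glycolysis, oxidative phosphorylation, cell cycle, ribosomal proteins, and off-lineage markers of monocytes, NK cells, T cells, B cells, neutrophils, platelets, erythroid cells and dendritic cells. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry; shorter lists were counted only. A list test is called by its adjusted p over lists, and each count of members is also given adjusted over the list alone where that differs. Shared genes are set beside the number that independent calls would share, which takes no account of people who gave cells to both groups of libraries. The off-lineage lists were also summarised per library as a mean log2 CPM with a prior count of 2, and compared by two-sided permutation tests with 100000 resamples, adjusted over 28 comparisons of arms and 32 of fractions. Correlations across libraries used permutation tests with 10000 resamples.

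Alternatives set in advance were RLE size factors, no low-count filter, a stricter filter, DESeq2 1.42.0, limma-voom with quality weights, the number of genes detected as a covariate, off-lineage marker levels as covariates, fits of only the groups compared and fits without the low-quality libraries. Added after the data were seen were an offset for GC content and gene length (a spline with 5 degrees of freedom per library), RLE size factors without the low-quality libraries, fits without the nearly empty libraries, and off-lineage covariates with the dendritic cell and erythroid lists. Other splits of the same libraries were refitted to see how many genes chance gives. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1. The median library had 1055689 gene reads (range 517 to 2820938). Reads carry no molecular identifiers, so this depth bounds counting error only.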

Results

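The data are gene read counts of 8 groups of libraries, made from 4 sorted blood fractions of healthy subjects and of patients after cardiac arrest. Tim-3-positive NK cells gave 12 healthy and 21 post-CA libraries, and Tim-3-negative NK cells gave the same numbers. Nectin-2-positive monocytes gave 11 healthy and 32 post-CA libraries, as did Nectin-2-negative monocytes. The median number of gene reads per library was 1049264 in healthy and 824645 in post-CA Tim-3-positive NK cells, and 1000513 and 893452 in Tim-3-negative NK cells. In Nectin-2-positive monocytes it was 1630644 in healthy and 1152019 in post-CA libraries, and in Nectin-2-negative monocytes 1582929 and 1540166. The series title names an axis of cytokines and immune checkpoints after cardiac arrest, and the comparisons ask how each sorted fraction differs between patients and healthy subjects.

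In Tim-3-positive NK cells, patients had more RNA of CXCR4 and FKBP5, genes known to respond to glucocorticoids, and less of CX3CR1 and SPN. CXCR4, the chemokine receptor that retains lymphocytes in bone marrow, rose by 3.41 ± 0.60 on the log2 scale (adjusted p = 8.48e-05), from 98.1 ± 87.2 to 1100 ± 1140 CPM (n = 12 and 20), and 18 of 20 patient libraries lay above the healthy median. FKBP5, a co-chaperone of the glucocorticoid receptor, rose by 2.33 ± 0.46 (adjusted p = 0.000558), from 69.7 ± 31 to 362 ± 279 CPM. CX3CR1, the fractalkine receptor of mature NK cells, fell by 1.03 ± 0.22 (adjusted p = 0.00143), from 2710 ± 419 to 1330 ± 579 CPM, with 20 of 20 patient libraries below the healthy median. SPN, the surface sialomucin CD43, fell by 1.66 ± 0.19 (adjusted p = 2.84e-09), from 448 ± 127 to 142 ± 64.2 CPM, also in 20 of 20 libraries.

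Of 11 tested glucocorticoid-responsive genes, 8 rose in post-CA Tim-3-positive NK cells and 0 fell (10 rose adjusted over the list alone), with a median log2 change of 1.64 (camera adjusted p = 9.31e-07; adjusted p = 0.283 with an estimated correlation). Examples besides CXCR4 and FKBP5 are DDIT4, a stress-induced inhibitor of mTOR signalling (1.57 ± 0.29, adjusted p = 0.000196), and PER1, a clock gene (1.90 ± 0.43, adjusted p = 0.00263). Of 14 CD56-dim NK markers, 2 fell (6 adjusted over the list alone), CX3CR1 and TBX21, the transcription factor T-bet (-0.56 ± 0.17, adjusted p = 0.0273). That list had a median of -0.44 (camera adjusted p = 0.00984; adjusted p = 0.69 with an estimated correlation). Among 14 cytotoxic effector genes 4 fell and 1 rose, the same counts adjusted over the list alone, and the list test did not pass (adjusted p = 0.221). NKG7, a granule membrane protein, changed by -0.47 ± 0.13 (adjusted p = 0.00942), GZMA, granzyme A, by -0.58 ± 0.16, and FASLG, the Fas ligand, by -0.72 ± 0.20. SRGN, the granule proteoglycan serglycin, rose by 0.78 ± 0.22. Among 20 NK receptors 4 fell, among them CD160 (-1.0 ± 0.31), SLAMF7 (-0.60 ± 0.17) and the signalling adaptor TYROBP (-0.49 ± 0.12), and KLRD1, the CD94 receptor chain, rose (0.55 ± 0.15). The list did not pass (adjusted p = 0.221). Of 10 NK cytokines and chemokines, CCL3 rose (1.22 ± 0.32, adjusted p = 0.00879), XCL2 fell (-1.14 ± 0.35, adjusted p = 0.0299), and IFNG, the gene of interferon-gamma, was measured at -0.74 ± 0.37 (adjusted p = 0.216). Of 18 oxidative phosphorylation genes 3 fell (3 adjusted over the list alone), NDUFB2, NDUFS3 and ATP5B. The list median was -0.24 (camera adjusted p = 0.00188; adjusted p = 0.69 with an estimated correlation).

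Another large rise in post-CA Tim-3-positive NK cells was in SOCS1, a feedback inhibitor of cytokine signalling that stayed low in level (2.65 ± 0.51, adjusted p = 0.000269, 9.22 ± 6.38 CPM in patients). CREM, FAM46C, PDE3B, IL7R and TMEM2 rose by 1.94 to 2.95. The immediate early gene IER2 fell by 2.14 ± 0.35 (adjusted p = 3.38e-05), and SLC9A3R1, MATK, TBCB, FPGS, YDJC, PRELID1, CST3 and COTL1 changed by -2.0 to -1.66. Single monocyte and platelet transcripts rose as well: S100A8 rose by 3.55 ± 1.04, VCAN by 3.0 ± 0.90, CD14 by 3.50 ± 1.02 and PPBP by 5.07 ± 1.65. The median PPBP level was 3.12 CPM in patients and 1.5 CPM in healthy subjects. Of 10 monocyte markers 4 rose (5 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.386). Per library, the monocyte list level differed between arms by 0.48 log2 CPM (permutation p = 0.439, adjusted p = 0.512). The platelet list level differed by 0.44 (permutation p = 0.341, adjusted p = 0.415), so neither list passed. Across genes, which are not independent replicates, the log2 change correlated with GC content at rho = -0.33 and with gene length at rho = 0.37. The median GC content was 42.0% in genes that rose and 56.3% in genes that fell. In all, 432 genes rose and 538 fell. With RLE size factors 686 rose and 385 fell, with DESeq2 1154 and 549, and without the low-quality libraries 833 and 736. With the offset for GC content and gene length 223 rose and 324 fell. The list tests, among them that of oxidative phosphorylation genes, were run without this offset.

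In Tim-3-negative NK cells FKBP5 and CXCR4 again rose and CX3CR1 fell, and the RNA of HAVCR2, the gene of the sorting marker itself, rose. FKBP5 rose by 2.67 ± 0.47 (adjusted p = 0.000867), from 56.7 ± 23.8 to 381 ± 317 CPM (n = 12 and 20), and CXCR4 by 2.83 ± 0.57 (adjusted p = 0.00424), in 19 of 20 patient libraries. Of 11 glucocorticoid-responsive genes 6 rose and 0 fell (9 rose adjusted over the list alone), with a median of 1.67 (camera adjusted p = 3.82e-08; adjusted p = 0.136 with an estimated correlation). With off-lineage covariates that median was 0.62 and 3 of the 6 calls held. CX3CR1 fell by 1.05 ± 0.22 (adjusted p = 0.0049), from 1860 ± 371 to 892 ± 464 CPM, in 20 of 20 libraries. HAVCR2 rose by 1.26 ± 0.29 (adjusted p = 0.00986), from 129 ± 46.0 to 321 ± 178 CPM, in 16 of 20 libraries. In the Tim-3-positive cells it was measured at 0.62 ± 0.28 (adjusted p = 0.16).

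Of 7 inflammatory cytokine genes in Tim-3-negative NK cells, 2 rose (4 adjusted over the list alone), CCL3, a chemokine for monocytes (1.86 ± 0.35, adjusted p = 0.00173), and TNFAIP3, an inhibitor of NF-kB signalling (2.10 ± 0.49, adjusted p = 0.01). The list rose with a median of 0.71 (camera adjusted p = 0.00138; adjusted p = 0.136 with an estimated correlation). SOCS1 rose by 3.06 ± 0.50 (adjusted p = 0.000198). Of 14 immediate early genes 4 rose (6 adjusted over the list alone), among them DUSP2, NR4A2 and FOS with changes of 2.37, 2.92 and 1.97, and the list did not pass (adjusted p = 0.0537). ENTPD1, the ectonucleotidase CD39, rose by 3.27 ± 0.70 (adjusted p = 0.00517). Of 14 CD56-dim markers 2 fell (4 adjusted over the list alone), CX3CR1 and FGFBP2 (-0.95 ± 0.26). The list fell with a median of -0.26 (camera adjusted p = 0.000289; adjusted p = 0.311 with an estimated correlation). Of 14 cytotoxic effectors 2 fell, NKG7 (-0.53 ± 0.13) and GZMA (-0.59 ± 0.16), and 1 rose (4 and 1 adjusted over the list alone). This list fell with a median of -0.21 (camera adjusted p = 0.0475; adjusted p = 0.462 with an estimated correlation). Of 20 NK receptors 2 fell, SLAMF7 (-0.65 ± 0.17) and TYROBP (-0.45 ± 0.12), with a median of -0.32 (camera adjusted p = 0.00138; adjusted p = 0.311 with an estimated correlation). C16orf54 fell by 1.00 ± 0.15 (adjusted p = 2.79e-05), and PRSS23, ANXA6, PLEKHF1, CXCR1 and ZNF600 changed by -1.13 to -0.85.

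The largest rises in Tim-3-negative NK cells were in platelet and monocyte transcripts. PPBP, a platelet chemokine, rose by 8.38 ± 1.84 (adjusted p = 0.00656), to a mean of 1170 ± 4040 and a median of 8.87 CPM. SDPR, F13A1, TUBB1, CLU, PTGS1, CD36, S100A8, RGS18 and SLC40A1 rose by 5.17 to 7.80. Both tested platelet markers rose, and of 10 monocyte markers 4 rose (9 adjusted over the list alone), with a median of 2.96 (camera adjusted p = 0.000356; adjusted p = 0.408 with an estimated correlation). Per library, the platelet list was higher by 1.41 log2 CPM in patients (3.30 ± 2.56 against 1.89 ± 0.38, permutation p = 0.0194, adjusted p = 0.109), and the monocyte list by 1.20 (p = 0.0138, adjusted p = 0.109). Gene length correlated with the log2 change across genes at rho = 0.25, and GC content at rho = -0.12. In all 194 genes rose and 83 fell, but limma-voom gave 116 and 177. Without the low-quality libraries 567 genes passed. With off-lineage marker levels as covariates 69 genes passed, 57 of them also without covariates, and RGS18 and SLC40A1 changed sign. For single genes such as HAVCR2 and ENTPD1, RNA of monocytes in these libraries is not separated from a change of NK cells.

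The 2 NK fractions shared 96 genes that rose after cardiac arrest, where independent calls would share 7.5, and 50 that fell, against 4.0; no gene went in opposite directions. The fractions may come from the same people, so a number above that of independent calls does not by itself show a shared response. The difference of the post-CA effect between Tim-3-positive and Tim-3-negative cells passed for 0 genes in edgeR, where 529 genes had an unadjusted p under 0.05; DESeq2 gave 3 genes and limma-voom 0. For HAVCR2 that difference was -0.64 ± 0.39 (adjusted p = 1).

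**Figure D1:**
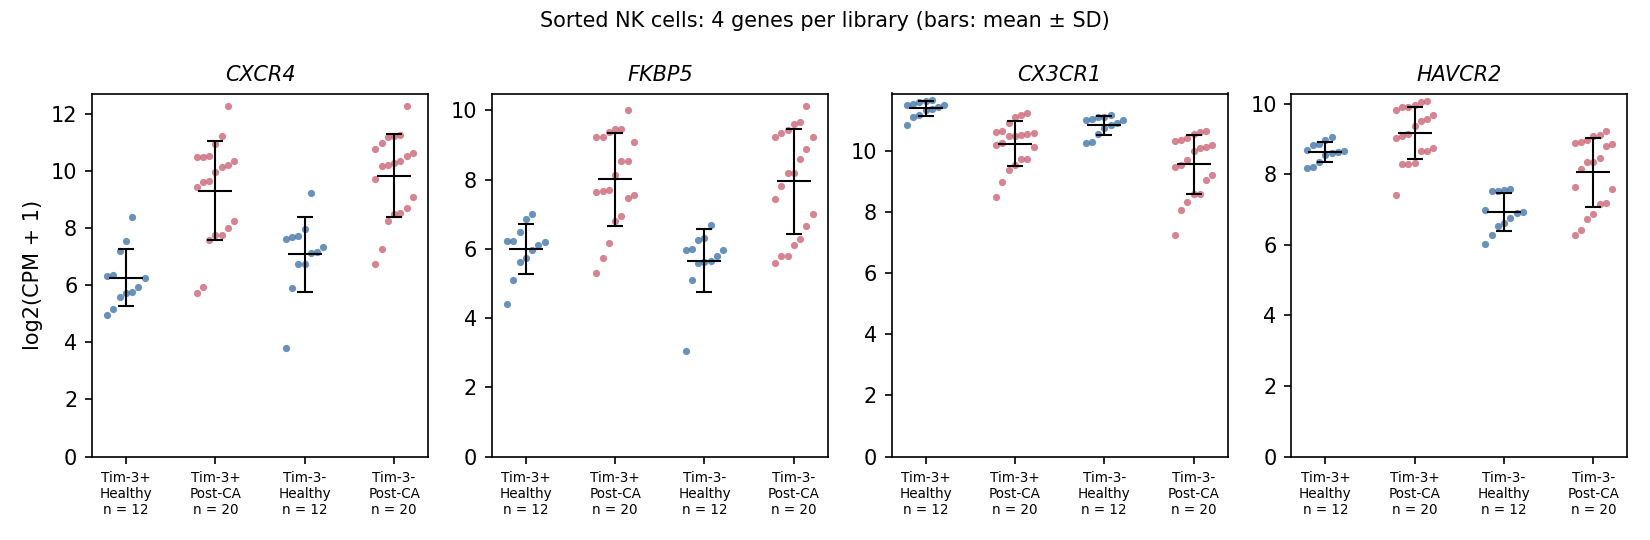
Each point is the log2(CPM + 1) level of CXCR4, FKBP5, CX3CR1 or HAVCR2 in 1 NK library (y axis) by group (x axis: Tim-3-positive healthy n = 12 and post-CA n = 20, Tim-3-negative healthy n = 12 and post-CA n = 20, low-quality libraries left out), with the mean and SD. CXCR4 and FKBP5 lie higher and CX3CR1 lower in patients in both fractions, and HAVCR2 passed the test only in the Tim-3-negative fraction (1.26 ± 0.29), while the test of the difference between fractions did not pass (-0.64 ± 0.39, adjusted p = 1).

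In Nectin-2-positive monocytes of patients, alarmin genes, the scavenger receptor CD163 and the decoy receptor IL1R2 rose. IL1R2, a decoy receptor for interleukin-1, rose by 6.43 ± 1.43 on the log2 scale (adjusted p = 0.00164). CD163, which takes up haemoglobin, rose by 3.45 ± 0.60 (adjusted p = 8.33e-05), from 175 ± 106 to 1770 ± 1890 CPM (n = 11 and 29), in 27 of 29 patient libraries. ADM, the vasodilator peptide adrenomedullin, rose by 4.13 ± 0.62 (adjusted p = 7.64e-06), from 8.53 ± 3.71 to 117 ± 118 CPM. IL10, an anti-inflammatory cytokine, rose by 3.15 ± 0.67 (adjusted p = 0.000995), to 17.2 ± 29.3 CPM. NECTIN2, the sorting marker, rose by 2.42 ± 0.46 (adjusted p = 0.000202), from 3.46 ± 1.87 to 16.5 ± 12.6 CPM, in 25 of 29 libraries.

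Of 12 alarmin and immature monocyte genes 10 rose and 0 fell in Nectin-2-positive monocytes (11 rose adjusted over the list alone), with a median of 1.64 (camera adjusted p = 5.38e-09; adjusted p = 0.164 with an estimated correlation). S100A8, a subunit of calprotectin, rose by 1.82 ± 0.36 (adjusted p = 0.000402), from 1600 ± 915 to 5760 ± 3980 CPM, MCEMP1 by 2.55 ± 0.44 and THBS1, thrombospondin 1, by 6.23 ± 1.18. Of 13 glucocorticoid-responsive genes 8 rose (11 adjusted over the list alone), with a median of 1.97 (camera adjusted p = 6.2e-06; adjusted p = 0.25 with an estimated correlation). Besides CD163 and IL1R2, FKBP5 rose by 1.82 ± 0.35 and DDIT4 by 4.37 ± 0.93. Of 20 hypoxia and glycolysis genes 11 rose (12 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 0.000244; adjusted p = 0.25 with an estimated correlation). They included SLC2A3, a glucose transporter (2.33 ± 0.47), and GAPDH (1.00 ± 0.23). Of 14 inflammatory cytokine genes 6 rose (10 adjusted over the list alone), with a median of 1.76 (camera adjusted p = 0.0287; adjusted p = 0.592 with an estimated correlation). CXCL8, CXCL2 and TNFAIP3 rose by 4.03, 2.98 and 1.41. Of 12 classical monocyte markers 5 rose (5 adjusted over the list alone; camera adjusted p = 0.0152; adjusted p = 0.592 with an estimated correlation), such as CD14 (1.83 ± 0.35) and VCAN (1.33 ± 0.30). The median of that list was 0.37, and 0.00 with RLE size factors. Of 19 pattern recognition genes 5 rose (6 adjusted over the list alone), among them the formyl peptide receptors FPR1 (1.45 ± 0.26) and FPR2 (1.39 ± 0.28), and CASP1, caspase-1, fell (-0.73 ± 0.21). The list did not pass (adjusted p = 0.128).

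Among 11 immune checkpoint genes of Nectin-2-positive monocytes, NECTIN2 and C10orf54, the gene of VISTA (0.50 ± 0.16), rose (4 adjusted over the list alone) and CD244 fell (-0.78 ± 0.24), and the list did not pass (adjusted p = 0.603; with RLE size factors 1 rose and 2 fell). Other genes that rose were RNASE1, CLU, METTL7B, G0S2 and VSIG4, a complement receptor (4.2 ± 0.87, 29 of 29 libraries), and FCGR1A, the high-affinity IgG receptor (1.95 ± 0.33, 29 of 29). IER2, ALDH1A1, ADGRE3, ITM2B, NOA1, INSIG1, ANTXR2, NAP1L1, SLC9A3R1 and CYSLTR1 changed by -1.42 to -1.08. The NK marker list was lower by 0.95 log2 CPM in these patient libraries (2.20 ± 0.52 against 3.14 ± 0.77, permutation p = 0.0001, adjusted p = 0.0028), and lower than the healthy median in 31 of 32. Of its 5 tested members 3 fell (4 adjusted over the list alone), such as PRF1, perforin (-2.40 ± 0.71), and NKG7 rose (2.28 ± 0.64). The list test did not pass (adjusted p = 0.131). Of 3 erythroid genes 2 rose (3 adjusted over the list alone), HBA2 (4.75 ± 1.62) and ALAS2 (4.37 ± 1.28). Across genes the log2 change correlated with GC content at rho = 0.43, with a median GC content of 55.3% in genes that rose and 42.3% in genes that fell. In all 987 genes rose and 417 fell. RLE size factors, which moved the median of all genes by -0.26, gave 308 and 974, and DESeq2 317 and 870. Without the low-quality libraries RLE gave 742 and 252 with a median shift of 0.03.

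In Nectin-2-negative monocytes of patients many of the same genes rose, and 7 of 10 HLA class II genes fell. IL1R2 rose by 6.94 ± 1.58 (adjusted p = 0.00322), from 8.05 ± 8.18 to 992 ± 2140 CPM (n = 9 and 32). The median of its patient libraries was 68.2 CPM, far below their mean. S100A8 rose by 1.89 ± 0.36 (adjusted p = 0.000523), from 3990 ± 1010 to 13000 ± 8040 CPM, in 31 of 32 libraries. NECTIN2 rose by 2.48 ± 0.51 (adjusted p = 0.00101), from 3.04 ± 2.17 to 17.6 ± 13.8 CPM, in 31 of 32 libraries. HLA-DPA1, an HLA class II chain, fell by 1.18 ± 0.30 (adjusted p = 0.00884), from 2130 ± 875 to 863 ± 652 CPM, in 31 of 32 libraries.

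Of these 10 HLA class II genes 0 rose (9 fell adjusted over the list alone), with a median of -1.08 (camera adjusted p = 3.22e-11; adjusted p = 0.078 with an estimated correlation). They included HLA-DQA1 (-1.77 ± 0.48), HLA-DMB (-1.24 ± 0.31), which loads peptides, and CIITA, the class II transactivator (-1.19 ± 0.33). The dendritic cell genes CD1C (-1.26 ± 0.31) and FCER1A (-2.43 ± 0.61) fell as well, 2 of the 4 tested from the dendritic cell list (3 adjusted over the list alone). In Nectin-2-positive monocytes 0 of the 10 HLA class II genes passed (median -0.28, adjusted p = 0.131), or 2 with RLE size factors, which both fell. Of 12 alarmin and immature monocyte genes 8 rose (11 adjusted over the list alone), with a median of 1.64 (camera adjusted p = 3.41e-12), and this call held with an estimated correlation (adjusted p = 0.0401). MCEMP1 rose by 2.15 ± 0.45 and S100A12 by 1.68 ± 0.43. Of 13 glucocorticoid-responsive genes 10 rose (10 adjusted over the list alone), with a median of 2.09 (camera adjusted p = 3.43e-05; adjusted p = 0.162 with an estimated correlation). They included FKBP5 (2.09 ± 0.38), CD163 (2.38 ± 0.59) and MERTK, a receptor for apoptotic cells (2.35 ± 0.53). Of 12 classical monocyte markers 4 rose (4 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 1.13e-05; adjusted p = 0.16 with an estimated correlation), and VCAN rose by 1.42 ± 0.30. The monocyte marker list, which shares 9 of the 12 classical markers with it, also rose, with a median of 0.83 (6 of 12 members, and 1 fell adjusted over the list alone; camera adjusted p = 1.07e-06; adjusted p = 0.0413 with an estimated correlation).

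Of 20 hypoxia and glycolysis genes 4 rose in Nectin-2-negative monocytes (8 adjusted over the list alone), ADM (3.30 ± 0.65), LDHA (1.25 ± 0.28), SLC2A3 and GAPDH. The list median was 0.36 (camera adjusted p = 0.000952; adjusted p = 0.193 with an estimated correlation). Of 14 inflammatory cytokine genes 3 rose (6 adjusted over the list alone), IL10 (4.10 ± 0.85, 32 of 32 libraries), CXCL2 and NFKBIA. This list had a median of 1.10 (camera adjusted p = 0.034; adjusted p = 0.556 with an estimated correlation). Of 19 pattern recognition genes 3 rose (5 adjusted over the list alone), TLR2 (0.81 ± 0.17), FPR1 and FPR2. The median of the list was 0.15 (camera adjusted p = 0.0151; adjusted p = 0.238 with an estimated correlation). Of 7 cytotoxic effector genes 3 rose (4 adjusted over the list alone, where 1 fell), NKG7 (3.51 ± 0.78), CST7 (4.17 ± 1.00) and SRGN (1.12 ± 0.26). Their list had a median of 0.65 (camera adjusted p = 0.0205; adjusted p = 0.0942 with an estimated correlation). METTL7B, CLU, RNASE1, THBS1, FAM20A, C1QB, DDIT4 and MS4A4A rose by 3.31 to 6.51, and ADGRE3, TPPP3, ALDH1A1, PID1 and SLFN5 changed by -2.02 to -1.08. In all 507 genes rose and 167 fell, and 445 and 179 without the 2 nearly empty healthy libraries, but limma-voom gave 783 and 910. With off-lineage covariates that include the dendritic cell and erythroid lists 110 genes passed, 77 of them also without covariates.

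The 2 monocyte fractions shared 306 genes that rose after cardiac arrest, against 43.9 for independent calls, and 47 that fell, against 6.1; no gene went in opposite directions. These fractions may come from the same people too. The difference of the post-CA effect between the fractions passed for 0 genes in edgeR, where 880 genes had an unadjusted p under 0.05; DESeq2 gave 1 gene, limma-voom 14, and edgeR with off-lineage covariates 242. For NECTIN2 that difference was -0.06 ± 0.61 (adjusted p = 1).

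**Figure D2:**
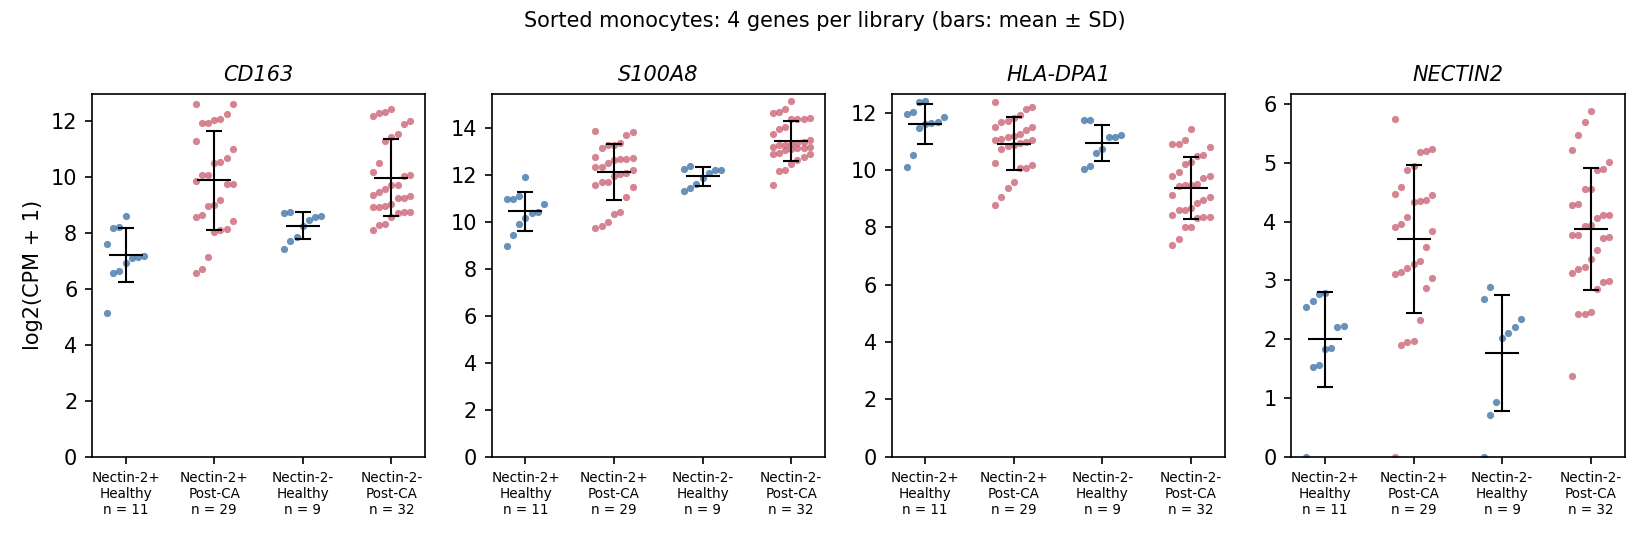
Each point is the log2(CPM + 1) level of CD163, S100A8, HLA-DPA1 or NECTIN2 in 1 monocyte library (y axis) by group (x axis: Nectin-2-positive healthy n = 11 and post-CA n = 29, Nectin-2-negative healthy n = 9 and post-CA n = 32, low-quality libraries left out), with the mean and SD. CD163, S100A8 and NECTIN2 lie higher in patients in both fractions, and HLA-DPA1 passed the test only in the Nectin-2-negative fraction, where it changed by -1.18 ± 0.30, while the test of the difference between fractions did not pass (0.67 ± 0.45, adjusted p = 0.718).

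Tim-3-positive and Tim-3-negative NK cells were compared within each arm to show which genes go with the sorting marker. As a list, markers of CD56-bright NK cells, a less mature subset, were lower in Tim-3-positive cells, and most tested HLA class II and dendritic cell transcripts were higher. GZMK, granzyme K, changed by -2.75 ± 0.39 log2 in patients (adjusted p = 2.93e-06, 19 of 20 libraries below the Tim-3-negative median) and by -3.19 ± 0.50 in healthy subjects (adjusted p = 7.3e-05, 12 of 12). FCER1A, the IgE receptor alpha chain of dendritic cells, was higher by 6.06 ± 0.85 in patients (adjusted p = 2.93e-06) and by 7.83 ± 1.32 in healthy subjects (adjusted p = 0.000183). HAVCR2 was higher by 1.00 ± 0.24 in patients (adjusted p = 0.00563, 16 of 20) and by 1.64 ± 0.32 in healthy subjects (adjusted p = 0.00131, 12 of 12).

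Of 13 CD56-bright markers 6 were lower in patients (8 adjusted over the list alone; median -0.87, camera adjusted p = 1.13e-14) and 4 in healthy subjects (7 adjusted over the list alone, where 1 was higher; median -0.96, camera adjusted p = 1.4e-13). Both calls held with an estimated correlation (adjusted p = 0.00326 and 0.00506). TCF7, a transcription factor of less mature lymphocytes, changed by -1.72 ± 0.27 in healthy subjects. The CD56-dim list was higher in patients with a median of 0.34 (1 of 14 members, 6 adjusted over the list alone). Its camera adjusted p was 0.000116, and 0.437 with an estimated correlation. In healthy subjects its median was 0.27 (0 of 14 members, 1 adjusted over the list alone). The camera adjusted p there was 0.000528, and 0.138 with an estimated correlation. Of 10 HLA class II genes 8 were higher in each arm (10 adjusted over the list alone). The medians were 1.78 in patients (camera adjusted p = 4.2e-07; adjusted p = 0.437 with an estimated correlation) and 2.35 in healthy subjects (camera adjusted p = 3.36e-16; adjusted p = 0.0361 with an estimated correlation). HLA-DRA was higher by 3.09 ± 0.58 in patients and CD1C by 5.24 ± 0.73. All 4 tested dendritic cell genes were higher in both arms. Per library the dendritic cell list was higher by 1.31 log2 CPM in patients (permutation adjusted p = 0.00299, 16 of 21 above the Tim-3-negative median) and by 2.23 in healthy subjects (adjusted p = 0.00032, 11 of 12). The B cell list differed by -0.71 in patients (adjusted p = 0.0102, 18 of 21). The T cell list differed by -0.48 in healthy subjects (adjusted p = 0.00667, 11 of 12). The monocyte list was higher by 1.54 in healthy subjects (adjusted p = 0.00397, 12 of 12) and by 0.83 in patients (adjusted p = 0.361, 14 of 21). In healthy subjects 2 of 10 monocyte markers were higher (5 adjusted over the list alone), with a median of 1.90 (camera adjusted p = 2.82e-07; adjusted p = 0.121 with an estimated correlation). Classical monocyte markers had a median of 2.29 there (2 of 11 higher, and 6 higher and 1 lower adjusted over the list alone; camera adjusted p = 8.83e-06; adjusted p = 0.138 with an estimated correlation). In patients 142 genes were higher and 308 lower, in healthy subjects 91 and 34. Of these genes 69 and 23 were shared, against 1.2 and 0.9 for independent calls. With limma-voom 127 were higher and 136 lower in healthy subjects. With off-lineage covariates 52 genes passed in healthy subjects and 265 in patients.

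Over the Tim-3-positive libraries, the HLA class II list level rose with the dendritic cell list level. In the 21 post-CA libraries r was 0.93 (permutation p = 0.0001, the smallest these permutations can give; adjusted p = 0.0001) and rho 0.91 (p = 0.0001, adjusted p = 0.0002). In the 12 healthy libraries r was 0.96 (p = 0.0001, adjusted p = 0.0001) and rho 0.86 (p = 0.0013, adjusted p = 0.0013). Without the 2 libraries farthest from the median dendritic cell level r was 0.91 and 0.93. The post-CA libraries left a gap in the dendritic cell level between 2.99 and 3.85. Within the 12 libraries below it r was 0.67 (p = 0.025) and rho 0.54 (p = 0.074), and within the 9 above it r was 0.93 (permutation p = 0.0003) and rho 0.90 (permutation p = 0.0024).

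**Figure D3:**
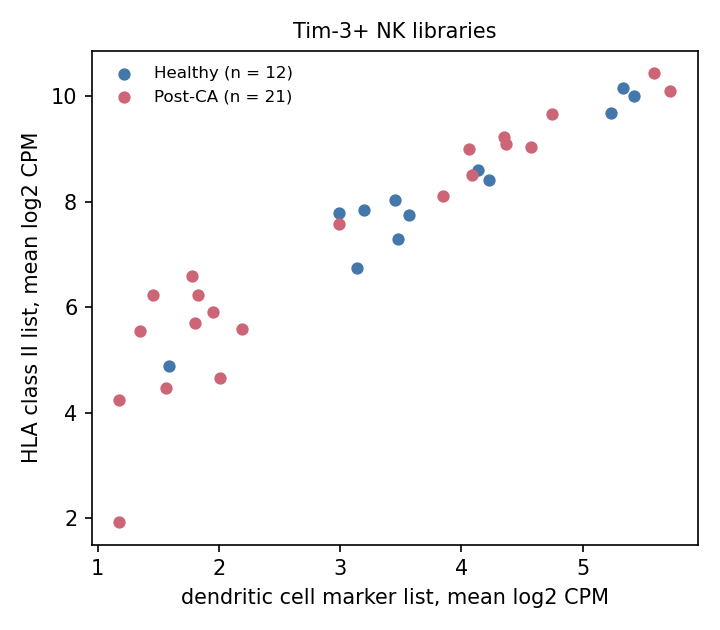
Each point is 1 Tim-3-positive NK library (12 healthy, 21 post-CA), with the mean log2 CPM of the dendritic cell list on the x axis and of the HLA class II list on the y axis. The 2 lists rise together in both arms (rho = 0.86 in healthy and 0.91 in post-CA libraries).

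Nectin-2-positive monocytes had more RNA of genes of the non-classical monocyte subset than Nectin-2-negative ones. FCGR3A, the CD16 receptor that marks this subset, was higher in the positive fraction by 3.02 ± 0.29 log2 in patients (adjusted p = 2.57e-13, 1770 ± 1200 against 204 ± 168 CPM, 29 of 29 libraries). In healthy subjects it was higher by 4.12 ± 0.55 (adjusted p = 6.98e-07, 11 of 11). The complement genes C1QA, C1QB and C1QC were higher by 3.94 to 4.54 in patients and by 5.39 to 6.36 in healthy subjects. NECTIN2 itself was measured at 0.12 ± 0.27 in patients (adjusted p = 0.783) and 0.18 ± 0.59 in healthy subjects (adjusted p = 0.99), at 16.5 ± 12.6 against 17.6 ± 13.8 and 3.46 ± 1.87 against 3.04 ± 2.17 CPM.

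Of 11 non-classical markers 10 were higher in patients (11 adjusted over the list alone; median 1.46, camera adjusted p = 3.58e-15). In healthy subjects 7 were higher (10 adjusted over the list alone; median 1.31, camera adjusted p = 2.11e-25). Both calls held with an estimated correlation (adjusted p = 0.00269 and 1.26e-05). Of 12 classical markers 10 were lower in patients (10 adjusted over the list alone; median -0.86, camera adjusted p = 6.07e-08; adjusted p = 0.0755 with an estimated correlation). In healthy subjects 0 classical markers passed (7 lower adjusted over the list alone; median -0.83, camera adjusted p = 7.99e-08; adjusted p = 0.0552 with an estimated correlation). HLA class II genes were higher in 8 of 10 in patients (9 adjusted over the list alone; median 0.98, camera adjusted p = 1.13e-07; adjusted p = 0.199 with an estimated correlation). The dendritic cell genes moved the same way in patients (2 of 4 higher, 3 adjusted over the list alone, median 0.60), and their list level was higher by 0.25 (permutation p = 0.0175, adjusted p = 0.0621, 21 of 32). In healthy subjects 0 of the 10 passed (median 0.28, camera adjusted p = 0.0498; adjusted p = 0.648 with an estimated correlation). CLEC4D, a pattern recognition receptor, changed by -1.88 ± 0.22 in patients and -1.80 ± 0.38 in healthy subjects, and STEAP4 by -1.95 ± 0.31 and -1.90 ± 0.53. MARC1, IER2 and DUSP1 were lower in patients, and ALOX5AP, DYSF and ADAM19 in healthy subjects. The NK marker list was higher by 1.49 log2 CPM in healthy Nectin-2-positive libraries (permutation adjusted p = 0.00667, 11 of 11 above the Nectin-2-negative median). By camera with an estimated correlation, CD56-dim (adjusted p = 4.52e-05), NK receptor (adjusted p = 0.012) and NK marker lists (adjusted p = 0.012) were higher there too. In each of these lists 1 member passed (3 NK receptors adjusted over the list alone). FCGR3A and CX3CR1 are in both the CD56-dim and the non-classical list. In patients the Nectin-2-positive libraries had lower levels of the neutrophil list (-0.24, adjusted p = 0.00397, 25 of 32) and of the monocyte list (-0.64, adjusted p = 0.00032, 30 of 32). All 3 tested erythroid genes were higher in patients, with a median of 2.96, while the erythroid list level was higher by 0.33 (adjusted p = 0.575). In patients 1857 genes were higher and 1469 lower, in healthy subjects 118 and 30. Of these genes 107 and 28 were shared, against 19.2 and 3.9. With limma-voom 422 were higher and 544 lower in healthy subjects. With off-lineage covariates 17 genes passed in healthy subjects and 1592 in patients. RLE size factors, which moved the median of all genes by -0.25, gave 615 and 3269 in patients, DESeq2 590 and 3218, and limma-voom 1619 and 1632. Without the low-quality libraries RLE gave 1678 and 1241 with a median shift of 0.03. The log2 change correlated with GC content at rho = 0.38 and with gene length at rho = -0.21 across genes.

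**Figure D4:**
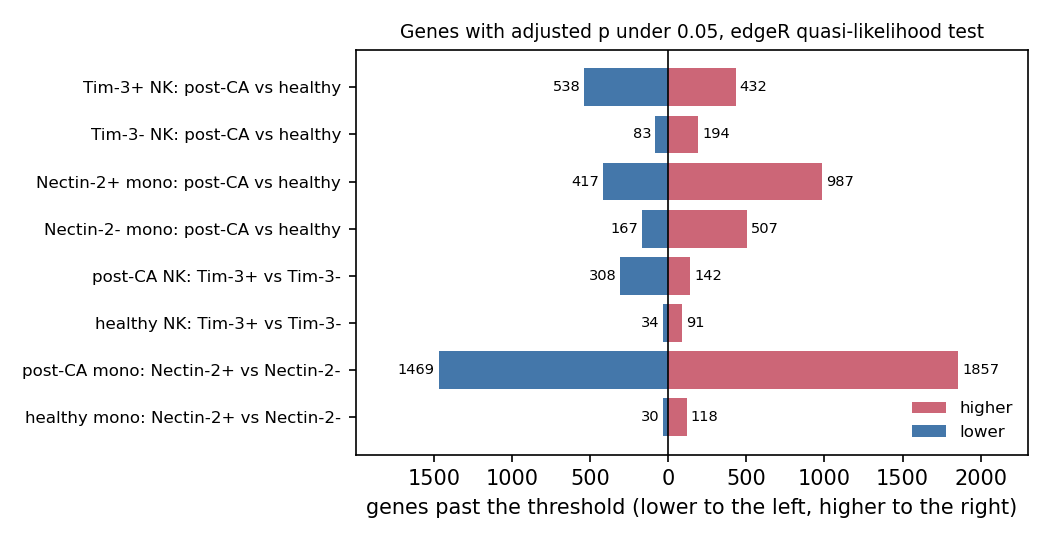
Bars give the number of genes that passed the test (x axis) in each of 8 comparisons (y axis). Genes higher in the first group named run to the right of 0 and genes lower in it to the left. The counts run from 125 genes for the NK fractions of healthy subjects to 3326 for the monocyte fractions of patients.

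The post-CA effect, averaged over the fractions of a lineage, was compared between monocytes and NK cells to show where it differs between their libraries. It differed for 1597 genes, 1007 with a more positive effect in monocytes and 590 with a more positive effect in NK cells. NKG7 had the largest difference towards monocytes (3.43 ± 0.48, adjusted p = 9.67e-08). It rose in both monocyte fractions and fell in both NK fractions. The largest differences towards NK cells were in PPBP, a platelet marker (-5.25 ± 1.17, adjusted p = 0.000698), and F13A1, which is not in the platelet list (-5.22 ± 0.83, adjusted p = 1.64e-06). Of 6 platelet markers 5 went this way (6 adjusted over the list alone), and of 12 monocyte markers 8 (10 adjusted over the list alone). Neither list passed (camera adjusted p = 0.179 and 0.061). RNA of platelets and monocytes in the NK libraries is not separated here from a response of NK cells. The difference was -0.44 ± 0.23 for HAVCR2 (adjusted p = 0.205) and 1.88 ± 0.68 for NECTIN2 (adjusted p = 0.0524). RLE size factors moved the median of all genes by -0.34 and gave 256 genes towards monocytes and 2194 towards NK cells, and DESeq2 288 and 3314. RLE scales by genes with reads in every library, only 92 of those tested here. Without the low-quality libraries 7772 such genes were left, and RLE gave 912 and 837. The trend of the post-CA effect with GC content differed in sign between lineages. Its rho was -0.33 in Tim-3-positive and -0.12 in Tim-3-negative NK cells. In monocytes it was 0.43 in the Nectin-2-positive and 0.05 in the Nectin-2-negative fraction. GC content may thus contribute to the difference between lineages.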

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

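The tests of monocyte RNA and of GC content and gene length for the glucocorticoid-responsive genes, the tests of a lower NK share and of monocytes inside the Tim-3-positive gate, and the fits of HLA class II genes with covariates and without the low-quality libraries, were chosen only after the results were seen. For the glucocorticoid-responsive genes, an earlier test that asked whether the interval of the list median stayed beyond 50% of its value was undecided, and those tests took its place. For monocytes inside the gate an earlier test took the median of the 4 dendritic cell genes (164% and 169% needed), and the genes were then parted by their own values.

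The post-CA effect differed between monocytes and NK cells for 1597 genes by the test of that difference, in which a single library has no direction. Towards monocytes, the largest differences in log2 change were in NKG7 (3.43 ± 0.48, adjusted p = 9.67e-08), LAIR2 (3.41 ± 0.97, adjusted p = 0.0104), S1PR1 (3.27 ± 0.58, adjusted p = 1.94e-05), IL18R1 (3.08 ± 0.74, adjusted p = 0.00204) and FAM20A (2.90 ± 0.48, adjusted p = 4.45e-06). Towards NK cells they were in PPBP (-5.25 ± 1.17, adjusted p = 0.000698), F13A1 (-5.22 ± 0.83, adjusted p = 1.64e-06), SDPR (-5.04 ± 1.11, adjusted p = 0.000677), TUBB1 (-4.66 ± 0.88, adjusted p = 5.22e-05) and PF4 (-4.06 ± 1.26, adjusted p = 0.0197). For such genes, platelet or monocyte RNA in the NK libraries is not separated from a response of NK cells. NKG7 lay above the healthy median in 31 of 32 Nectin-2-negative post-CA libraries and below it in 19 of 20 Tim-3-positive ones, and PPBP above it in 15 of 20 Tim-3-negative ones. Among lists, alarmin and immature monocyte genes had a median difference of 0.42 (camera adjusted p = 0.0256; adjusted p = 0.931 with an estimated correlation), with a mean of -0.17 and a median of -0.13 with RLE size factors. Oxidative phosphorylation genes had 0.33 (camera adjusted p = 9.83e-05; adjusted p = 0.931 with an estimated correlation), and -0.03 with RLE size factors. Type I interferon-stimulated genes had -0.24 (camera adjusted p = 0.0207; adjusted p = 0.931 with an estimated correlation).

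Between the NK fractions, 4 lists differed in their post-CA effect, each with a more negative effect in Tim-3-positive cells. The median differences were -1.35 for classical monocyte markers (camera adjusted p = 0.019), -0.53 for HLA class II genes (0.0127), -0.68 for immediate early genes (0.019) and -1.48 for off-lineage monocyte markers (0.0127), and the adjusted p was 0.816 for each with an estimated correlation. Between the monocyte fractions, CD56-dim NK markers differed by -0.91 (camera adjusted p = 0.0172), which held with an estimated correlation (adjusted p = 0.0391), but 0 of the 6 tested members passed (1 fell adjusted over the list alone). Of the 14 genes of this list 4 are also off-lineage NK markers, which differed by -1.17 (camera adjusted p = 0.0708). The level of those markers differed between arms by -0.95 in Nectin-2-positive and 0.33 in Nectin-2-negative monocytes, so a change of NK cell RNA in the libraries and a change of monocytes are not separated. HLA class II genes differed by 0.74 (camera adjusted p = 0.00047; adjusted p = 0.528 with an estimated correlation), with less of a fall in Nectin-2-positive cells. Across genes these differences between fractions correlated with GC content at rho = -0.28 in NK cells and 0.41 in monocytes.

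Of 11 glucocorticoid-responsive genes 8 rose in post-CA Tim-3-positive and 6 in Tim-3-negative NK cells, and their list mean lay above the healthy median in 20 of 21 Tim-3-positive and 17 of 21 Tim-3-negative libraries. Monocyte RNA could not account for the called members other than CD163 and IL1R2 as a set: the median rise needed monocyte RNA amounting to 156% of the Tim-3-positive and 191% of the Tim-3-negative RNA (lowest 20% and 24.9%), whereas LYZ, an abundant monocyte transcript, allowed 1.68% and 0.176% by its median level (by mean levels 120% and 118% against 6.01% and 1.14%, where PER1 in Tim-3-positive cells, at 32.3%, lay within 10 times the LYZ value and stays open). Set against the monocyte fraction with less LYZ, its mean level in Tim-3-positive cells allowed 10.7%. By mean levels FKBP5 (65.1%) and TSC22D3 (91.2%) in these cells then lay within 10 times that value too and stay open. For CD163 and IL1R2 monocyte RNA may account for the rise, at least in part. By median levels IL1R2 needed 14.2% and 1.52%, more than LYZ allowed but within 10 times that value. CD163 needed 2.73% and 0.174%. By mean levels CD163 and IL1R2 needed 2.84% and 3.07% in Tim-3-positive cells, where LYZ allowed 6.01%. In Tim-3-negative cells they needed 1.36% and 1.61%, where LYZ allowed 1.14%. With the offset for GC content and gene length the medians were 1.83 and 1.76, and 7 of 8 and 5 of 6 calls held, which argues against that bias as the whole cause, although the intervals over members (0.75 to 3.05 and 0.64 to 2.88) reached below 0.82 and 0.84, the value at 50% of the main medians. With off-lineage covariates the Tim-3-negative median was 0.62 and 3 of 6 calls held (Tim-3-positive 1.44, 6 of 8); endogenous or given glucocorticoids, treatment and the unlabelled batches stay open, as untested.

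Dendritic cell transcripts were higher in Tim-3-positive than in Tim-3-negative NK cells in both arms. A lower share of NK cells with an even rise of all other cell types would raise their lists alike. In patients the data argue against such an even rise, because the B cell list differed by -0.71 (permutation adjusted p = 0.0102, lower in 18 of 21 libraries). They do not address a lower share of NK cells in which only some other cell types rise, such as those that the gate itself lets in. In healthy subjects the T cell list differed by -0.48 (permutation adjusted p = 0.00667) and the monocyte list by 1.54. The B cell list there differed by -0.55 (permutation adjusted p = 0.209) and the platelet list by 0.09 (permutation adjusted p = 0.842). The healthy libraries thus rest on the T cell list, in which RNA of T cells and of NK cells is not separated, and do not decide. Monocytes inside the gate could not account for FCER1A and CD1C, whose mean rise needed monocyte RNA amounting to at least 244% where the mean level of LYZ, set against the monocyte fraction with less of it, allowed 10.7% in patients and 9.51% in healthy subjects, but monocytes and dendritic cells cannot be told apart as a source of CLEC10A and SERPINF1 (41.9% to 93.2%) or of part of the HLA class II rise (31.9% and 30.7%), all within 10 times what LYZ allows. Dendritic cells inside the Tim-3-positive gate may account for the HLA class II rise, since the lists correlated in both arms (lower rho = 0.86, permutation p = 0.0013, adjusted p = 0.0013). With the dendritic cell list as a covariate the HLA class II medians went from 1.78 to -0.48 in patients and from 2.35 to -0.49 in healthy subjects, with 0 of 8 calls held in each. That fit cannot decide the source. The list itself differed between fractions by 1.31 in patients and 2.23 in healthy subjects, so as a covariate it also takes up fraction differences of other sources. None of the 8 genes of the dendritic cell list is in another list, the labels do not describe the gates, and an NK cell state with these transcripts stays open, as untested.

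Of 10 HLA class II genes 7 fell in post-CA Nectin-2-negative monocytes, with the list mean below the healthy median in 28 of 32 libraries. GC content and gene length were not the whole cause, since the offset left a median of -1.05 with 7 of 7 calls held. The values also argue against a shift from non-classical to classical cells as the whole cause. With the non-classical level as a covariate the median was -1.11 (interval over members -1.27 to -0.81) and 7 of 7 calls held. Without the low-quality libraries that median was -1.15, and the non-classical level differed between arms by -0.02 (permutation p = 0.944). With all libraries that level differed by 0.67 (permutation p = 0.0646). An interval over members gives the spread between genes that move together (estimated correlation 0.737), not the error over libraries. With the dendritic cell list as a covariate the median moved from -1.08 to -0.88 (interval over members -1.03 to -0.54), the median SE from 0.31 to 0.33 and 0 of 7 calls held, and without the low-quality libraries the median moved from -1.15 to -0.96 (interval -1.15 to -0.71) and 1 of 8 calls held. Fewer dendritic cells in the gate and a fall within monocytes cannot be told apart, because the first of these intervals reaches -0.54, 50% of the main median, and the dendritic cell list itself differed by -0.25 in patients (permutation p = 0.168, adjusted p = 0.324), or by -0.57 without the low-quality libraries (permutation p = 0.0001, adjusted p = 0.00196; 30 of 32 libraries below the healthy median with all libraries). Lower class II expression of patient monocytes stays open as the biological explanation.

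Other splits of the same libraries were fitted to see whether chance gives as many genes. They exchange libraries as if independent, although some patients gave more than 1 library to a monocyte fraction, and chance is excluded only on that footing. In the 4 comparisons of post-CA with healthy libraries chance can be so excluded, since 1 of 50 splits, the real one, reached the real count: 970 genes in Tim-3-positive NK cells (highest other split 2), 277 in Tim-3-negative NK cells (159), 1404 in Nectin-2-positive monocytes (424) and 674 in Nectin-2-negative monocytes (25). The same held for the fractions: 450 genes in patient NK cells (highest other 93), 125 in healthy NK cells (0), 3326 in patient monocytes (412) and 148 in healthy monocytes (0). For the difference between lineages 1 of 25 splits reached 1597 genes (highest other 82). For the differences between fractions the real count was 0 genes, which all 40 of 40 splits reach by construction, so the splits say nothing about chance there (highest other 70 in NK cells and 1 in monocytes). Single splits with many genes, such as this one with 70 and those with 159, 424 and 412, may follow a structure of the samples, which was not tested.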

How the results depend on the processing

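The offset for GC content and gene length, RLE size factors without the low-quality libraries, fits without the nearly empty libraries and off-lineage covariates with the dendritic cell and erythroid lists were chosen only after the data were seen. Over all settings, 282 results of named genes gave 3381 values: 2840 kept direction and side of the threshold, 514 lost the call, 7 gained one and 20 changed sign. Losses were most frequent with the wider off-lineage covariates (98), no low-count filter (87), limma-voom (81) and the planned off-lineage covariates (72). Except where stated, the cause was not tested. With unstated strand handling and a median of 1055689 gene reads, genes of low level and genes with overlapping neighbours are the least certain. The pseudocount alternative was not run, since the table holds counts; fits of only the groups compared do not apply to differences of effects, and the lineage difference took T cell, neutrophil and platelet covariates only.

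Counts of genes more than 1.5 times away from the main ones were as follows. In post-CA against healthy Tim-3-positive NK cells (main 970) DESeq2 gave 1703, limma-voom 1651, fits without the low-quality libraries 1569, RLE without them 1582 and the GC and length offset 547. In Tim-3-negative NK cells (main 277) DESeq2 gave 632, fits without the low-quality libraries 567, RLE without them 573, only the groups compared 130, off-lineage covariates 69 and the wider covariates 89. In Nectin-2-positive monocytes (main 1404) the number of genes detected as a covariate gave 677, no filter 684 and only the groups compared 865. In Nectin-2-negative monocytes (main 674) limma-voom gave 1693, no filter 402 and the wider covariates 110. Fits of only the groups compared use fewer libraries. With limma-voom the balance of directions turned in Tim-3-negative NK cells (116 rose and 177 fell) and in Nectin-2-negative monocytes (783 and 910).

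Between NK fractions of patients (main 450) only the groups compared gave 166, off-lineage covariates 265 and the wider covariates 197; in healthy subjects (main 125) DESeq2 gave 198, limma-voom 263, only the groups compared 400, the stricter filter 51, off-lineage covariates 52 and the wider covariates 21. Between monocyte fractions of patients (main 3326) the genes detected covariate gave 1513, off-lineage covariates 1592 and the wider covariates 1673; in healthy subjects (main 148) limma-voom gave 966, only the groups compared 611, the stricter filter 96, off-lineage covariates 17 and the wider covariates 20. For the difference between NK fractions (main 0) DESeq2 gave 3 and no filter 5, and between monocyte fractions (main 0) DESeq2 gave 1, limma-voom 14, no filter 3, off-lineage covariates 242 and the wider covariates 331. For the difference between lineages (main 1597) RLE gave 2450 and DESeq2 3602. Both scale by genes with reads in every library. Over all monocyte libraries these were 148 of the genes tested, and 9128 without the low-quality libraries. Off-lineage marker levels differed between arms for 2 lists without the low-quality libraries, against 1 with them.

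Some log2 changes took the opposite sign. NECTIN2 between monocyte fractions of patients was 0.12 in the main test, -0.285 with DESeq2, -0.27 with RLE, -0.069 with RLE and -0.079 with TMM without the low-quality libraries, -0.147 with the GC and length offset and -0.116 with off-lineage covariates. In healthy subjects it was -0.031 with DESeq2 and -0.01 with the wider covariates, which gave 0.026 for its difference between fractions. HAVCR2 between monocyte fractions of patients was -0.019 with DESeq2 and -0.02 with RLE. In Tim-3-negative NK cells RGS18 was -0.553 and SLC40A1 -0.237 with off-lineage covariates, and -0.313 and -0.146 with the wider ones. With the wider covariates CXCL2 was -0.336 in Nectin-2-positive monocytes, HLA-DQA1 -0.12 and HLA-DRA -0.246 between NK fractions of patients, and HLA-DQA1 -0.046 in healthy subjects. HBB between monocyte fractions of patients was -0.872 with off-lineage covariates.

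Of 86 list calls by camera, 12 held with an estimated correlation and 74 did not, while fry kept 52 and lost 34. For the post-CA effect, an estimated correlation left 0 called lists in Tim-3-positive NK cells (main 3), 0 in Tim-3-negative NK cells (main 10), 0 in Nectin-2-positive (main 7) and 2 in Nectin-2-negative monocytes (main 11). Between NK fractions it left 1 in patients (main 6) and 3 in healthy subjects (main 16), and between monocyte fractions 1 (main 11) and 4 (main 13). For differences of the effect it left 0 between NK fractions (main 4), 1 between monocyte fractions (main 2) and 0 between lineages (main 3). With fry, Tim-3-negative NK cells had 6 lists, NK fractions 2 in patients and 10 in healthy subjects, healthy monocyte fractions 6 and the difference between NK fractions 0.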

Other observations

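Genes of proliferation and of stress moved in part of the fractions. Of 10 cell cycle genes 2 rose in each post-CA monocyte fraction, MKI67, a proliferation marker, and BIRC5, survivin, both at low levels of 3.98 to 8.94 CPM in patients. MKI67 rose by 2.91 ± 0.94 in Nectin-2-positive cells (adjusted p = 0.0304, 19 of 29 libraries above the healthy median). In Nectin-2-negative cells it rose by 3.37 ± 0.98 (adjusted p = 0.0234, 28 of 32). In Nectin-2-negative cells MCM3 (-0.59 ± 0.18, adjusted p = 0.0377, 27 of 32 below) and MCM4, helicase subunits of DNA replication, fell (3 rose and 3 fell adjusted over the list alone), and the list passed in neither fraction (adjusted p = 0.954 and 0.44). In Tim-3-positive NK cells of patients 4 of 13 cell cycle genes were higher than in Tim-3-negative ones (5 adjusted over the list alone). Their median was 0.47 (camera adjusted p = 0.000393, and 0.483 with an estimated correlation). In healthy subjects 0 of the 13 passed, and the median was 0.445 (camera adjusted p = 0.000303, and 0.17 with an estimated correlation). Of 15 heat shock genes 3 rose in Nectin-2-positive monocytes (6 adjusted over the list alone), HSPA5, the chaperone of the endoplasmic reticulum (1.15 ± 0.35, adjusted p = 0.0225, 21 of 29 above), HSPA1B and HSPB1. In Nectin-2-negative monocytes 2 rose, BAG3 and HSPB1. Neither list test passed (adjusted p = 0.487 and 0.0758).

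Type I interferon-stimulated genes had a median of -0.28 in post-CA Nectin-2-positive monocytes, where 1 of 20 fell, DDX58, the RNA sensor RIG-I (-0.85 ± 0.28, adjusted p = 0.0331, 27 of 29 below; 0 adjusted over the list alone). In Nectin-2-negative monocytes the median was -0.26 and 0 passed. The list tests gave camera adjusted p = 0.0029 and 0.0017, and adjusted p = 0.72 and 0.644 with an estimated correlation. Of 14 interferon-gamma response genes in Nectin-2-negative monocytes FCGR1A rose (1.49 ± 0.34, adjusted p = 0.00319, 31 of 32 above) and CIITA fell, with a list median of -0.18 (camera adjusted p = 0.034; adjusted p = 0.74 with an estimated correlation). Ribosomal protein genes were lower in Tim-3-positive than in Tim-3-negative NK cells of patients (3 of 20, 5 adjusted over the list alone). Their median was -0.19 (camera adjusted p = 4.78e-06, and 0.483 with an estimated correlation). In healthy subjects 0 of 20 passed (1 was lower adjusted over the list alone). The median there was -0.16 (camera adjusted p = 2.19e-05, and 0.344 with an estimated correlation).

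Across lineages, Tim-3-positive NK cells and Nectin-2-positive monocytes shared 53 genes that rose in patients, against 28.8 for independent calls, and 48 that fell, against 19.4, while 43 went in opposite directions. Tim-3-negative NK cells and Nectin-2-negative monocytes shared 34 that rose, against 6.1, and 1 that fell, against 1.0, with 6 opposite. Tim-3-positive NK cells and Nectin-2-negative monocytes shared 52 that rose, against 13.7, and only 2 that fell, against 7.4, with 27 opposite. For Tim-3-negative NK cells and Nectin-2-positive monocytes these were 52, against 12.8, and 10, against 2.6, with 9 opposite. For the post-CA effect, the median, the mean and the direction of the camera test differed in sign for some lists, of which none passed. They were alarmin and immature monocyte genes in both NK fractions (medians 0.16 and 0.24, means 1.12 and 2.11, direction down), immediate early genes in Tim-3-positive NK cells, heat shock genes and non-classical monocyte markers in Tim-3-negative NK cells, and the checkpoint axis, interferon-gamma response, type I interferon-stimulated and off-lineage NK lists in both NK fractions. In Nectin-2-positive monocytes they were CD56-bright markers, cytotoxic effectors, interferon-gamma response, NK cytokines and NK receptors, and in Nectin-2-negative monocytes cell cycle, the checkpoint axis, NK receptors and off-lineage NK markers.

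Some other off-lineage list levels differed between arms at an unadjusted p under 0.05, and none passed after adjustment. T cell markers differed by -0.41 log2 CPM in post-CA Tim-3-negative NK cells (permutation p = 0.0249, adjusted p = 0.116) and by -0.31 in Nectin-2-positive monocytes (p = 0.00508, adjusted p = 0.0711). B cell markers differed by -0.43 in Nectin-2-positive monocytes (p = 0.0461, adjusted p = 0.143). In Nectin-2-negative monocytes erythroid markers were higher by 0.57 (p = 0.0178, adjusted p = 0.109), platelet markers by 0.71 (p = 0.0289, adjusted p = 0.116) and neutrophil markers by 0.25 (p = 0.045, adjusted p = 0.143). Without the 2 nearly empty healthy libraries these values were 0.55 (p = 0.059), 0.47 (p = 0.171) and 0.05 (p = 0.597). Of 2 to 4 tested neutrophil genes 0 passed between arms in any fraction, and adjusted over the list alone 1 fell in Tim-3-negative NK cells. The share of ambiguous reads was lower in post-CA Tim-3-positive NK libraries (0.516 ± 0.0956% against 0.671 ± 0.126%, permutation p = 0.00026, adjusted p = 0.00416 over 16 tests), and 21 of 21 lay at or below the healthy median. The share without an annotated feature was 60.3 ± 3.48% against 57.5 ± 2.01% in the same libraries (p = 0.0198, adjusted p = 0.129).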
